A study of Mus musculus with 34 samples.

How the data were processed

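The series measured RNA abundance in mouse cells with Affymetrix expression arrays. Per the labels' protocols, total RNA was purified on RNeasy columns with DNase treatment, amplified by 2 rounds of in vitro transcription and labelled with biotin. The deposited table holds log2 values, 1 per probe set and array, which the authors made with RMA (robust multi-array average: background correction, normalization between arrays and a summary over the probes of a probe set). The submitters' processing notes give no version of it. On the MEF arrays 13 probe sets exceed 16, the highest log2 value of a 16-bit scanner, so a further adjustment of unstated kind after RMA is possible. Arrays carry no read depth; their number limits the precision of each mean.

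The table has 34 columns and 12488 probe sets, of which 66 are controls. ESC replicate 3 equals the mean of ESC replicates 1 and 2 in every probe set, and PGC E11.5 replicate 5 equals the mean of replicates 1 to 4, both within a tolerance of 1e-06. These 2 columns were left out, which left 32 arrays in 10 groups. The plan made before the data were examined had counted all 34, which is given as an alternative. Groups follow the labels, which call the replicates biological. The labels give replicate numbers no meaning across groups. Correlations of like-numbered residuals ran from -0.566 to 0.521 over pairs of groups. All lay above 0.1 for PGC E11.5 with MEF (4 numbers, 0.104 to 0.269) and EGC with PGC E13.5 female (3 numbers, 0.125 to 0.347), which no comparison sets against each other alone. Among pairs of groups compared alone, they did so for ESC with ICM, which share 2 numbers (0.161 and 0.176). Numbers were therefore not taken as pairs, and the block is an alternative.

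The platform table gives exactly 1 gene symbol for 10833 probe sets, several for 396 and none for 1193. Symbols were brought up to date by gene ID with the gene table of assembly GRCm38.p6 for 10817 of them, and 16 kept the symbol of the file. Chromosomes also come from that table; no coordinates were used. Each gene was represented by its brightest probe set over the 32 arrays, giving 8251 genes, of which 2073 had more than 1 probe set. No gene was removed for low signal in the main test. The table gives no detection calls, so where a gene stands at background in 1 of the groups compared, its fold is only a rough measure.

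Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings), with all 10 groups sharing 1 estimate of spread. That fit had 22 residual degrees of freedom, 4.78 prior degrees of freedom and a median residual SD of 0.161. A gene was called at an adjusted p under 0.05 (Benjamini-Hochberg over 8251 genes, two-sided). The count called with at least a 2-fold difference is given beside it. Pluripotent over somatic contrasts the mean of 6 group means with the mean of 4. A shared pluripotent gene had to be higher, or lower, in each of the 6 pluripotent groups than in each of the 4 somatic groups; its p is the largest of 24 one-sided p-values, adjusted over genes. The other 8 comparisons are differences of group means, the last of them a difference of 2 differences. All errors of differences are standard errors (SE) from limma; errors of group means are standard deviations (SD) over arrays.

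A set of 26 gene lists, with 644 entries of which 471 were measured, was fixed before the data were examined. It covers pluripotency; the germ cell and piRNA pathway; meiosis; male germ cell fate; primitive endoderm; trophectoderm; post-implantation and early lineage. It also covers gonad and mesonephros soma, mesenchyme and fibroblast, neural stem, haematopoietic stem, erythroid, endothelium and macrophage genes. The rest are Hippo components, YAP target genes, DNA methylation and demethylation, imprinted genes, glycolysis, oxidative phosphorylation, cell cycle, cell cycle inhibitors, immediate early and stress genes, LIF and BMP responses, maternal and 2-cell stage genes, and polycomb and repressors. Some genes stand in more than 1 list: Dcn is in the mesenchyme and the imprinted lists, and Lats2 and Amotl2 are in both the Hippo and the YAP lists. Coverage was low for some lists. Only 8 of 32 germ cell and piRNA genes, 8 of 30 meiosis genes, 6 of 15 male germ cell fate genes and 9 of 22 maternal genes were measured. Mael, Piwil2 and Tdrd1 of the germ cell and piRNA list were among those not measured, so the piRNA pathway was hardly assessed. Each list was tested per comparison with camera of limma (preset inter-gene correlation 0.01, two-sided, adjusted over the 26 lists) and again with an estimated correlation. Called members were counted over all genes and adjusted over the list alone. Genes of the X chromosome were tested as 1 set against autosomal genes in the female over male comparison.

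Named genes follow a rule set before the data were examined. Per comparison they are the 5 largest rises and 5 largest falls among called genes whose compared groups overlap in no array, and 10 per direction for the shared genes. From each list described, up to 4 called members with the largest difference and up to 2 uncalled members with the highest mean could be named. Markers of sex were read in groups labelled with 1 sex. A set of fixed genes could be named anywhere, among them Pou5f1, Nanog, Sox2, Klf4, Esrrb, Zfp42, Dppa3, Dppa5a, Ddx4, Dazl, Kit, Stra8, Lats2, Yap1, Gata6, Cdx2, Tet1 and Col1a1. Ddx3y, Nanos2, Dnmt3b and H19 are also in the rule but have no probe set with 1 symbol on this array.

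The pipeline was tested on simulated data of the same design with 200 changed genes of 8251. Of the genes changed 2-fold, 80.6% to 100% were recovered over the 10 comparisons. Of those changed 1.41-fold, 10.4% were recovered for the shared genes, 22.4% for the culture difference, 41.8% for EGC over ESC, 43.3% for ESC over ICM and 55.2% to 95.5% for the others, so smaller changes are often missed. Unchanged genes made up at most 7.89% of the calls. Camera found the 1 shifted list and none of the 25 unshifted lists. The simulated noise was independent between genes and, for each gene, equally wide in all groups. The simulation therefore does not test the effect of correlated list members or of groups that vary more, such as ICM.

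Alternatives planned beforehand were a mean over probe sets, probe sets that may cross-hybridise left out, dim genes left out, quantile normalization, centring each array on its median, array weights, eBayes with trend and robust, only the compared groups in the fit, the replicate number as a block, an estimated correlation in camera, each group left out, each germ cell group alone, and each array left out in turn. Added after seeing the data were all 34 columns, plain _at probe sets only, and the NSC and HSC arrays left out. Other splits of the arrays into groups were drawn with a fixed seed, at most 100 per comparison. Tables and plots were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.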

Results

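Gene expression was compared between 6 groups of mouse pluripotent cells, taken from embryos or grown as lines, and 4 groups of somatic cells. From embryos came the inner cell mass of the E3.5 blastocyst, dissected by immunosurgery (ICM, 3 arrays), and primordial germ cells sorted for an Oct4/GFP reporter. The germ cells were of mixed sex at E11.5 (PGC E11.5, 4 arrays) and sorted by sex at E13.5 (PGC E13.5 female, 3, and PGC E13.5 male, 3). The cultured lines were male embryonic stem cells (ESC, 2) and male embryonic germ cells derived from E12.5 germ cells (EGC, 3). The somatic groups were reporter-negative cells of the E11.5 gonad and mesonephros (SGM, 4) and embryonic fibroblasts of E13.5 (MEF, 6). Adult somatic groups were neural stem cells grown as neurospheres (NSC, 2) and bone marrow haematopoietic stem cells (HSC, 2). Strain was C57Bl/6 except in ICM, where crosses with other strains were used. Values are log2 units of signal per gene, and differences are log2 differences. The first principal component held 40.2% of the variance between arrays and the second 16.4%.

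**Figure D1:**
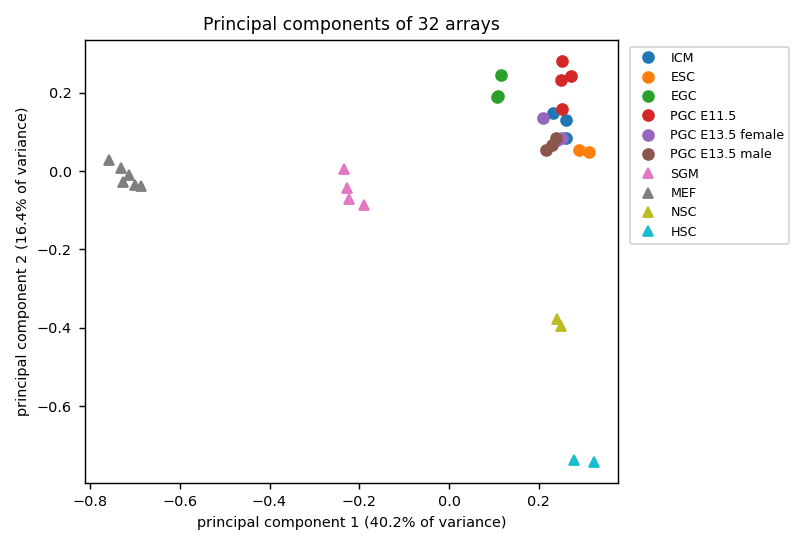
Each point is 1 of 32 arrays, placed by principal components 1 (40.2% of variance) and 2 (16.4%) of the deposited log2 values; circles are pluripotent groups and triangles somatic groups, coloured by group. All pluripotent arrays lie at the upper right, MEF and SGM to the left, and NSC and HSC below.

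Sex labels were read from Eif2s3y, a Y-linked gene, and Xist, the transcript that silences an X chromosome. Eif2s3y (log2, mean ± SD) was 3.76 ± 0.19 in PGC E13.5 female (n = 3) and 6.44 ± 0.32 in PGC E13.5 male (n = 3). It was 6.95 ± 0.31 in ESC (n = 2), 5.67 ± 0.37 in EGC (n = 3) and 8.02 ± 0.04 in HSC (n = 2), all labelled male. Xist was 5.29 in PGC E13.5 female and 5.28 in PGC E13.5 male, with SDs of 0.008 and 0.01, and so did not separate the sexes. The Y-linked genes Kdm5d and Uty passed no test between the E13.5 sexes (log2 differences -0.13 and -0.20).

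The pluripotent groups were set against the somatic groups to find what sets them apart on average. Dppa5a was 132-fold higher (log2 difference 7.04 ± 0.07 SE; 18 pluripotent against 14 somatic arrays) and the tumour antigen gene Trap1a 42.5-fold. Dppa2, a chromatin factor of early embryos, was 42.3-fold higher, Pou5f1 (Oct4, the core pluripotency factor) 33.6-fold and the F-box gene Fbxo15 29.3-fold. The largest falls were in Cd1d1, which presents lipid antigens (10.3-fold lower, -3.37 ± 0.12), Rasa3, a Ras GTPase-activating protein (8.63-fold), Eid1 (6.14-fold), Tmem176b (5.71-fold) and the transcription factor Tcf4 (5.33-fold). By the naming rule, these 10 were chosen among the 143 of 5273 called genes in which no pluripotent array overlapped a somatic one.

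Of 27 measured pluripotency genes, 24 rose and 1 fell (the same counts adjusted over the list alone; list test adjusted p = 4.47e-18). Nanog, a core factor, was 29.0-fold higher (4.86 ± 0.10) and Zfp42 8.61-fold. Sox2 was 28.8-fold higher on average (4.85 ± 0.07), yet it stood at 12.01 ± 0.23 (SD, n = 2) in NSC, above every pluripotent group mean. Esrrb (0.07) passed no test, and neither did Tbx3 (0.04), which was called higher without SGM (0.36) and lower without NSC (-0.17) or without the NSC and HSC arrays (-0.57). Group means of Esrrb ran only from 6.33 (ICM) to 6.83 (PGC E13.5 male), so its signal may not exceed background in any group. Klf4 was 1.73-fold lower, with means of 12.05 ± 0.16 in MEF (n = 6) and 7.64 ± 0.22 in PGC E11.5 (n = 4), and passed no test without MEF (-0.27). Germ cell and piRNA genes rose in 7 of the 8 measured (adjusted p = 2.44e-04, 7 over the list alone), led by Dppa3, a maternal protector of DNA methylation (24.3-fold), and the germ cell factor Tfap2c (6.62-fold). That list has 32 members, so most of it was not read.

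Cell cycle genes were higher in pluripotent cells: 27 of 29 rose and 1 fell (the same over the list alone; adjusted p = 1.71e-13). Examples are Cdc6, which licenses replication origins (4.43-fold), the spindle checkpoint kinase Bub1 (4.36-fold), Cdc20 (3.95-fold) and the mitotic kinase Aurka (3.34-fold). Cell cycle inhibitors fell in 10 of 14 (10 over the list alone; adjusted p = 0.00831), among them Cdkn1a (p21; 2.05-fold lower) and Rbl2 (1.72-fold lower). Ccng1 of the same list was 1.52-fold lower, but rose by 0.76 once MEF was left out. Polycomb and repressor genes rose in 14 of 18 and fell in 1 (the same over the list alone; adjusted p = 4.69e-04). Mtf2 and Suz12, parts of the polycomb complex that methylates histone H3, were 2.73-fold and 2.39-fold higher, and Phc1 and Jarid2 2.50-fold and 2.25-fold.

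Several somatic lists were lower in pluripotent cells, while the gonad and mesonephros (adjusted p = 0.169), erythroid (0.216), endothelial (0.249) and macrophage (0.0716) lists passed no test. Mesenchyme and fibroblast genes fell in 24 of 29 and rose in 1 (the same over the list alone; adjusted p = 1.03e-04), for example Postn (3.46-fold lower), Zeb1 (3.01-fold) and the proteoglycan genes Lum (2.98-fold) and Dcn (2.84-fold). Neural stem genes fell in 12 of 19 and rose in 2 (adjusted p = 0.00215), with Fabp7 3.47-fold lower (-0.09 without NSC, past no test) and Ptprz1 3.34-fold lower. Haematopoietic stem genes fell in 16 of 24 and rose in 1 (adjusted p = 0.00119), with Mllt3 2.88-fold and Meis1 2.50-fold lower. Counts over each list alone were equal for both lists. Immediate early and stress genes fell in 14 of 20 (14 over the list alone; adjusted p = 4.69e-04, but adjusted p = 0.107 with an estimated correlation), such as Fos (2.52-fold lower), Egr1 (2.50-fold) and Jun (2.48-fold). A second, dimmer Egr1 probe set was called the other way (0.11). Meiosis genes rose in 5 of 8 and fell in 1 (the same over the list alone; adjusted p = 0.031, or adjusted p = 0.203 with an estimated correlation and 0.0552 with the replicate number as a block), led by Syce2 (5.60-fold).

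In all, 5273 of 8251 genes passed limma's test, 2397 higher and 2876 lower in pluripotent cells, of which 358 and 375 by at least 2-fold. The actin control signal at the 3′ end exceeded that at the 5′ end by 0.95 to 1.86 in the pluripotent group means. PGC E13.5 male (0.39) was the exception, and the means were 0.70 in SGM and 0.47 in MEF. For Gapdh the pluripotent means ran from 2.65 to 4.00, with 3.08 in SGM and 2.66 in MEF. Neither was read in NSC and HSC. The calls for the pluripotency, germ cell, mesenchyme, neural stem, haematopoietic stem, cell cycle, inhibitor and polycomb lists held with an estimated correlation, with adjusted p-values up to 0.0496. Yap1, the effector of the Hippo pathway, was 1.21-fold higher here but fell by 0.64 without HSC, and its second probe set fell by 0.40. A mean over all probe sets of a gene made many named differences smaller here and in the other comparisons, such as Pou5f1 at 2.65 in place of 5.07.

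**Figure D2:**
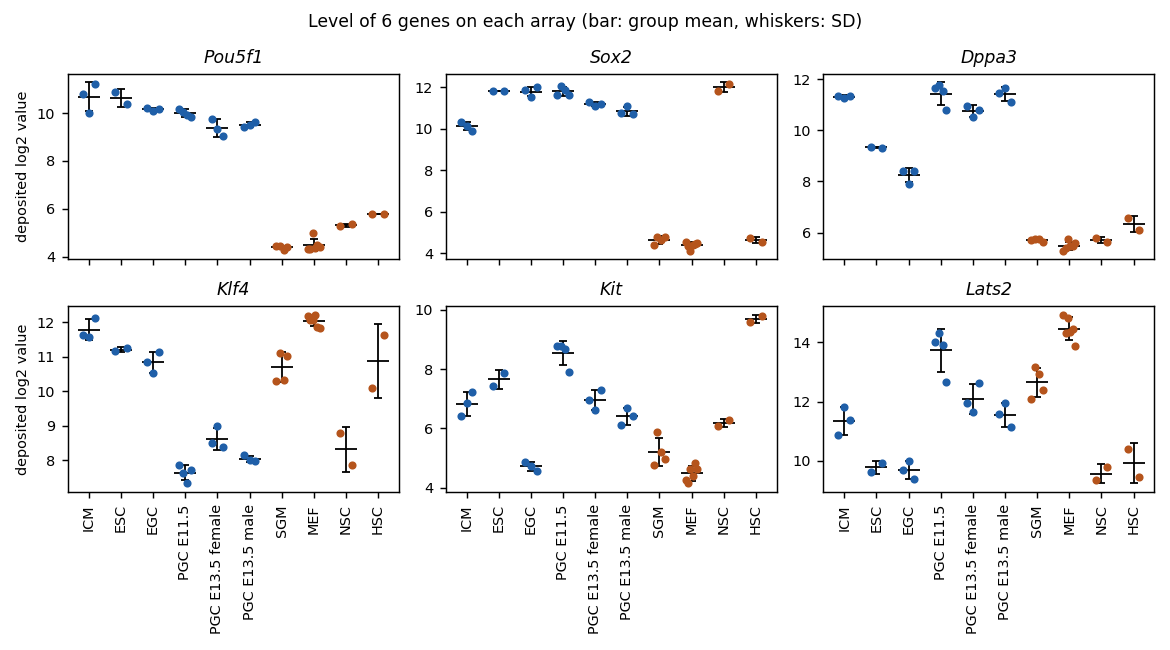
Deposited log2 value (vertical axes, each with its own range) of 6 genes on each of 32 arrays; horizontal axis groups are pluripotent (blue) and somatic (orange), bars are group means and whiskers SD. Pou5f1 and Dppa3 separate the 2 sets of groups, Sox2 is also high in NSC (12.01), Klf4 is lowest in PGC E11.5 (7.64), and Lats2 is higher in PGC E11.5 (13.73) than in ESC (9.79) or EGC (9.69). On PGC E11.5 replicate 2 Lats2 (14.31) is at the highest value of that array.

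A stricter comparison asked which genes every pluripotent group had above every somatic group. It found 34 shared higher genes and 13 shared lower genes, with a gap of at least 2-fold in 22 and 6. The widest gaps between the lowest pluripotent and the highest somatic group mean were in Dppa5a (72.8-fold), Trap1a (22.0-fold), Dppa2 (13.6-fold), Dppa4 (12.6-fold) and Pou5f1 (12.2-fold). Fbxo15 (3.53 on the log2 scale), Nanog (9.85-fold), Sall4, a zinc finger partner of Oct4 (5.00-fold), Dppa3 (3.73-fold) and the adhesion gene Epcam (3.38-fold) followed. Of the 27 pluripotency genes, 10 were shared, where 0.11 would be drawn at random (Fisher's exact test, adjusted p = 6.86e-17). They were Dppa2, Dppa4, Dppa5a, Gdf3, Mybl2, Nanog, Nr5a2, Pou5f1, Sall4 and Utf1; Mybl2 lost its call without NSC replicate 2 (0.74) or HSC replicate 2 (0.82), with array weights (0.71) and with a mean of probe sets (0.21). From the germ cell list, Dppa3 and Tfap2c were shared (2 of 8, Fisher's exact test, adjusted p = 0.0059).

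Shared lower genes had narrower gaps. Tmem176b was at least 3.48-fold lower in each pluripotent group than in each somatic group, Tmem176a 2.60-fold, the kinase gene Fyn 2.44-fold, Zhx1 2.37-fold and Nipsnap2 2.34-fold. Gabarapl1, an autophagy gene, had a gap of 2.29-fold, Nek6 1.83-fold, Adcy6 1.80-fold, Papss1 1.79-fold and Dnajb2 1.76-fold. The shared counts depend on the NSC and HSC groups: leaving out their 4 arrays gave 304 higher and 353 lower genes. With either ESC array left out, the shared lower genes numbered 8. Single arrays decided several of these calls: Papss1 and Dnajb2 lost theirs without ESC replicate 1 or 2, Papss1 without HSC replicate 2, Nek6 without ICM replicate 3, NSC replicate 1 or HSC replicate 1, Adcy6 without NSC replicate 2 or HSC replicate 1, and Zhx1 without NSC replicate 2. Their gaps were then between -0.59 and -0.99. Nek6 also lost its call with array weights (-0.81), with each array centred on its median (-0.74) and with the replicate number as a block (-0.84), and Zhx1 with a mean of probe sets (-0.19).

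Germ cells of E11.5 were set against the reporter-negative cells of the same region and stage. The sort used an Oct4 reporter, so Pou5f1 itself (49.0-fold higher, 5.62 ± 0.18 SE; 4 against 4 arrays) is not independent of the grouping. Sox2, which at 4.66 in SGM stood near its 4.63 in HSC and 4.39 in MEF, was 142-fold higher in germ cells (7.15 ± 0.13), Dppa5a 90.7-fold, Dppa3 53.0-fold and the X-linked homeobox gene Rhox5 48.5-fold. The gonad soma was richer in globin transcripts, with Hba-x 48.7-fold (-5.61 ± 0.21), Hba-a1 36.5-fold and Hbb-b2 36.3-fold lower in germ cells. The matrix gene Dcn was 35.5-fold lower and the immediate early gene Fos 27.1-fold lower.

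Pluripotency genes rose in 21 of 27 and fell in 2 (21 and 3 over the list alone; adjusted p = 2.93e-11), with Dppa2 32.3-fold higher and Nanog 30.8-fold. Klf4 was 8.33-fold lower in germ cells. Germ cell genes rose in 7 of 8 (8 over the list alone; adjusted p = 1.63e-07): Prdm1, a repressor that specifies germ cells, was 12.1-fold higher, the receptor gene Kit 10.1-fold and Tfap2c 8.58-fold, and Ddx4 4.30-fold. Ddx4 stood at 6.755 in PGC E11.5, near its 6.60 in ICM, 6.41 in ESC and 6.26 in HSC, and may not exceed background there. Cell cycle genes rose in 20 of 29 and none fell (the same over the list alone; adjusted p = 4.98e-07), with Cdc6 4.79-fold and the proliferation marker Mki67 4.36-fold higher. Polycomb genes rose in 10 of 18 and fell in 2 (the same over the list alone; adjusted p = 0.00977), with Eed, a core polycomb subunit, 6.70-fold higher. Male germ cell fate genes rose in 4 of 6 and fell in 1 (5 and 1 over the list alone; adjusted p = 0.0333, or adjusted p = 0.0659 with an estimated correlation), with Nodal 5.80-fold higher.

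Several somatic lists fell in germ cells. Mesenchyme genes fell in 24 of 29 and rose in 1 (the same over the list alone; adjusted p = 1.35e-10), including Postn (18.9-fold lower) and the collagens Col1a2 (13.9-fold) and Col3a1 (log2 difference -4.15). Gonad and mesonephros genes fell in 14 of 22 (14 over the list alone; adjusted p = 2.54e-04, but adjusted p = 0.0659 with an estimated correlation): the nuclear receptor genes Nr2f1 and Nr2f2 were 8.98-fold and 8.85-fold lower, Wt1, which is needed to form the gonad, 8.75-fold, and Wnt4 6.22-fold. Erythroid genes fell in 10 of 11 (10 over the list alone; adjusted p = 1.93e-05, and adjusted p = 0.0659 with an estimated correlation), including Hbb-y (21.3-fold lower) and the haem synthesis gene Alas2 (5.88-fold). Endothelial genes fell in 8 of 12 (8 over the list alone; adjusted p = 0.00172, and adjusted p = 0.124 with an estimated correlation), with Emcn 6.79-fold lower. Haematopoietic stem genes fell in 15 of 24 and rose in 1 (15 and 2 over the list alone; adjusted p = 0.017, and adjusted p = 0.126 with an estimated correlation), while Myb, the member that rose, was 10.1-fold higher in germ cells by a probe set ending in _s_at, and differed by 0.02 by the other.

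Hippo components fell in 10 of 18 and rose in 2 (the same over the list alone; adjusted p = 0.00397). Rassf1 was 4.92-fold lower, Amotl2 4.15-fold, Wwtr1 (TAZ) 3.97-fold and the YAP partner Tead2 3.81-fold; Yap1 was 2.49-fold lower and the kinase gene Lats2 2.11-fold higher. Imprinted genes fell in 17 of 24 and rose in 3 (17 and 4 over the list alone; adjusted p = 2.54e-04), with Mest 15.4-fold and Cdkn1c 11.9-fold lower. Igf2 was 13.0-fold lower by its brightest probe set, but differed by 0.07 when only plain _at probe sets were used. Immediate early genes fell in 14 of 20 and rose in 1 (15 and 1 over the list alone; adjusted p = 0.00122, or adjusted p = 0.124 with an estimated correlation), with Atf3 4.42-fold and Egr1 3.73-fold lower; a dimmer Atf3 probe set was called higher (0.35). Primitive endoderm genes fell in 14 of 26 and rose in 2 (the same over the list alone; adjusted p = 0.00776, or adjusted p = 0.319 with an estimated correlation), with Col4a1 13.8-fold lower. Trophectoderm genes fell in 10 of 21 (10 over the list alone; adjusted p = 0.0107, or adjusted p = 0.402 with an estimated correlation), with Krt19 6.21-fold lower.

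In this comparison 4141 genes passed limma's test, 1918 higher and 2223 lower in germ cells, 720 and 649 of them by at least 2-fold. The pluripotency, germ cell, mesenchyme, Hippo, imprinted, cell cycle and polycomb calls held with an estimated correlation, with adjusted p-values up to 0.0347. The 18S control signal was 12.86 ± 0.57 (SD) in PGC E11.5 and 14.68 ± 0.42 in SGM, and the actin 3′ minus 5′ signal 0.95 and 0.70, neither with overlap of arrays (n = 4 each).

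Female and male germ cells of E13.5 were compared at the stage when female cells enter meiosis and male cells do not. Stra8, which switches on meiosis, was 10.8-fold higher in female cells (3.43 ± 0.22 SE; 3 against 3 arrays). The imprinted gene Phlda2 was 12.9-fold higher, Id1, a target of BMP signals, 9.82-fold, Calcoco2, an autophagy receptor, 6.27-fold, and the desmosome gene Dsp 4.78-fold. Male cells were higher in the Y-linked Eif2s3y (6.42-fold lower in female cells, -2.68 ± 0.58) and in the Nodal pathway genes Lefty1 (3.87-fold) and Nodal (3.15-fold). Faap20, of the DNA crosslink repair complex, was 3.32-fold lower and the lipid kinase gene Dgka 2.70-fold lower in female cells.

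Meiosis genes rose in female cells in 4 of 8 and none fell (5 over the list alone; adjusted p = 1.20e-04). Besides Stra8 these were the synaptonemal gene Syce2 (1.63-fold), the meiotic cohesin gene Stag3 (1.63-fold) and Dmc1, a recombinase (1.44-fold). The Dmc1 call was lost without PGC E13.5 female replicate 3 (0.27), PGC E13.5 male replicate 1 (0.52) or PGC E13.5 male replicate 3 (0.49), and with only the compared groups in the fit (adjusted p = 0.172). Male germ cell fate genes fell in 2 of 6 (2 over the list alone; adjusted p = 0.00107), the 2 being Lefty1 and Nodal. LIF and BMP response genes rose in 4 of 17 and fell in 1 (the same over the list alone; adjusted p = 0.00262). Id1, Id2 (4.68-fold) and Id3 (2.94-fold), inhibitors of differentiation factors, moved with Gbx2 (2.49-fold). These 3 list calls held with an estimated correlation, with adjusted p-values up to 0.0299.

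Germ cell genes rose in 4 of 8 and fell in 1 (6 and 1 over the list alone; adjusted p = 0.00148, or adjusted p = 0.165 with an estimated correlation), with Tex19.1 2.25-fold and Ddx4 2.04-fold higher and Dppa3 1.57-fold lower in female cells. Ddx4 lost its call without PGC E13.5 female replicate 3 (0.54), and Dppa3 without female replicate 2 or 3 or male replicate 1 or 2 (-0.54, -0.66, -0.63 and -0.54). With only the compared groups in the fit both lost it (adjusted p = 0.15 and 0.0623). Ddx4 stood at 6.335 in female and 5.30 in male cells, near its 6.26 in HSC and 5.59 in NSC, and may not exceed background. Imprinted genes rose in 5 of 24 and fell in 1 (8 and 2 over the list alone; adjusted p = 0.00925, or adjusted p = 0.216 with an estimated correlation). The list's median difference was -0.01 and its mean 0.34, with the largest rises in Phlda2, Slc22a18 (4.07-fold) and the growth factor receptor Igf2r (2.23-fold). Post-implantation genes fell in 4 of 18 (4 over the list alone; adjusted p = 0.00548, or adjusted p = 0.229 with an estimated correlation), with Lhx1 1.42-fold lower. Gonad and mesonephros genes fell in 1 of 22 (1 over the list alone; adjusted p = 0.00647, or adjusted p = 0.229 with an estimated correlation), that gene being Lhx1. Cell cycle genes rose in 1 of 29 (4 rose and 1 fell over the list alone; adjusted p = 0.029, or adjusted p = 0.377 with an estimated correlation). The pluripotency genes Pou5f1 (-0.14), Nanog (0.04) and Sox2 (0.36) passed no test between the sexes, though Sox2 was called with array weights (0.37, adjusted p = 0.0494).

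X-linked genes were higher in female germ cells. The median log2 difference was 0.03 over 259 X-linked genes and -0.05 over 7971 autosomal genes (camera p = 9.16e-07, and 2.71e-04 with an estimated correlation). Among genes whose highest group mean reached the median signal, it was 0.28 over 160 X-linked genes and -0.01 over 5376 autosomal genes. Of these X-linked genes 68.1% lay above 0, against 48.0% of the autosomal ones. Over all X-linked genes, 58 were called higher in female cells and 1 lower.

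**Figure D3:**
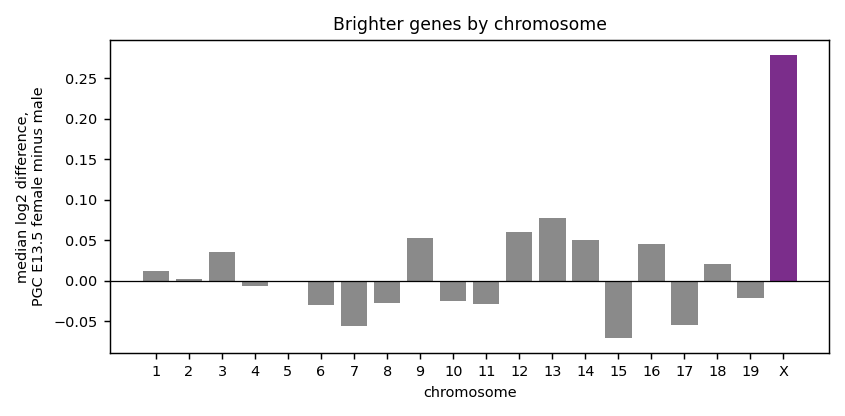
Median log2 difference between PGC E13.5 female and PGC E13.5 male (vertical axis) of the brighter genes on each chromosome (horizontal axis), 3 arrays per sex; each bar is 1 chromosome. The X chromosome stands at 0.28, and the autosomes lie between -0.07 and 0.08.

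Between the sexes 711 genes passed limma's test, 519 higher and 192 lower in female cells, 77 and 17 of them by at least 2-fold. Without PGC E13.5 female replicate 2 the 77 became 120, and without PGC E13.5 male replicate 2 the 192 became 124. After quantile normalization 336 genes were lower, 34 of them by at least 2-fold. The count rests on few arrays: it was 389 without PGC E13.5 female replicate 3, 414 without PGC E13.5 male replicate 3, and 1243 with array weights, 425 of them lower. The actin control signal at the 3′ end exceeded that at the 5′ end by 1.00 ± 0.30 (SD) in female and 0.39 ± 0.16 in male cells, with no overlap of arrays; the Gapdh control (3.81 ± 0.23 and 3.57 ± 0.44) overlapped.

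Germ cells of E13.5, both sexes averaged, were compared with those of E11.5. Stra8 was 4.76-fold higher at E13.5 (2.25 ± 0.17 SE; 6 against 4 arrays), with its clear rise in the female cells: 8.53 ± 0.81 (SD) in female and 5.11 ± 0.15 in male cells, against 4.57 ± 0.17 at E11.5. The male difference of 0.54 was called, but the male level lies near that of NSC (5.05), ESC (5.17) and HSC (5.43) and may be background. The phosphatase gene Dusp9 was 4.26-fold higher, the respiratory chain gene Ndufb8 3.86-fold, Gm1673 3.48-fold and Gstm5 3.08-fold. The nucleosome-binding gene Hmgn5 was 8.45-fold lower (-3.08 ± 0.23), the actin bundler Pls3 7.52-fold, Hpf1, a cofactor of PARP1, 6.31-fold and Mki67 5.82-fold. Eif2s3y was 6.27-fold lower on average, with 1 of the E13.5 groups female. It was also lower in PGC E13.5 male (6.44) than in PGC E11.5 (7.75), with no overlap of arrays, so the female group is not the whole cause.

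Pluripotency genes fell in 15 of 27 and rose in 3 (the same over the list alone; adjusted p = 3.16e-04, but adjusted p = 0.268 with an estimated correlation). Zfp42 was 4.94-fold lower, Nanog 2.39-fold, Sall4 2.33-fold, Sox2 1.72-fold and Pou5f1 1.47-fold (-0.37 and past no test after quantile normalization), while Dppa5a passed no test (-0.13). Germ cell genes fell in 6 of 8 and rose in 1 (the same over the list alone; adjusted p = 0.0023, or adjusted p = 0.268 with an estimated correlation), with Kit 3.61-fold and Prdm1 3.16-fold lower and Dazl, an RNA-binding protein of germ cells, 1.48-fold higher (0.33 in male cells alone, past no test). Glycolysis genes fell in 11 of 19 and rose in 3 (the same over the list alone; adjusted p = 0.0023, or adjusted p = 0.268 with an estimated correlation): Pfkp was 4.30-fold lower, Hk2 3.97-fold, Slc16a1, a lactate carrier, 2.78-fold and Ldha 2.34-fold. Cell cycle genes fell in 13 of 29 and rose in 3 (14 and 3 over the list alone; adjusted p = 0.00129, or adjusted p = 0.313 with an estimated correlation), including Bub1 (3.35-fold lower) and Rrm2, which makes DNA precursors (3.03-fold).

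Meiosis genes rose in 6 of 8 (6 over the list alone; adjusted p = 0.034, or adjusted p = 0.328 with an estimated correlation and 0.0877 with the replicate number as a block), with Stag3 2.04-fold and Sycp1 1.72-fold higher. Sycp1 lost its call without PGC E11.5 replicate 4 (0.51), PGC E13.5 female replicate 3 (0.45) or PGC E13.5 male replicate 1 (0.64). It also lost it with array weights (0.39), with the replicate number as a block (0.69), with only these groups in the fit (adjusted p = 0.134) and with male cells alone (0.32). Post-implantation genes rose in 11 of 18 (11 over the list alone; adjusted p = 0.034, or adjusted p = 0.431 with an estimated correlation and 0.073 with that block), with Gsc 1.48-fold higher. Endothelial genes rose in 9 of 12 (10 over the list alone; adjusted p = 0.0333, or adjusted p = 0.431 with an estimated correlation), with Emcn 1.69-fold higher. Lats2 was 3.75-fold lower at E13.5.

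In this comparison 4193 genes passed limma's test, 2549 higher and 1644 lower at E13.5, but of those changed at least 2-fold 50 were higher and 479 lower. Those 2-fold counts were 86 and 624 without PGC E11.5 replicate 4, 89 and 601 with array weights, and 95 and 420 after quantile normalization. The median over all genes was 0.12, and centring each array on its median moved the share of called genes that were higher from 60.8% to 46.4%. The 18S ribosomal RNA control signal also moved with stage, from 12.86 ± 0.57 (SD, n = 4) at E11.5 to 14.54 ± 0.36 in female and 15.06 ± 0.32 in male cells (n = 3 each). With the female group alone, 2602 genes passed, 101 higher and 384 lower by at least 2-fold; with the male group alone, 4326 passed, 55 higher and 632 lower by 2-fold.

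Embryonic stem cells were compared with the inner cell mass, the embryonic cells from which such lines are derived. Strain, sex and culture differ together here. The imprinted gene Peg3 was higher in ESC by 4.00 ± 0.26 (log2, SE; 2 against 3 arrays), Tceal9 12.1-fold, the amino acid carrier gene Slc38a2 10.9-fold, Pdk3, which restrains pyruvate oxidation, 8.99-fold and Epb41l4a 8.14-fold. Other probe sets gave 0.90 for Tceal9 and 0.80 for Epb41l4a (log2). Pramel6, a gene of the early embryo, was 45.9-fold lower in ESC (-5.52 ± 0.19), BC053393 28.9-fold, Calcoco2 22.5-fold, the homeobox gene Crxos 18.1-fold and the Ets factor Spic 14.9-fold.

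Glycolysis genes rose in 10 of 19 in ESC and none fell (11 over the list alone; adjusted p = 8.83e-05, or adjusted p = 0.0793 with an estimated correlation): Pfkp was 5.58-fold, Pdk1 5.30-fold, Pgk1 4.32-fold and Ldha 4.10-fold higher. Oxidative phosphorylation genes fell in 9 of 30 and rose in 1 (the same over the list alone; adjusted p = 0.0277, or adjusted p = 0.57 with an estimated correlation), with the complex I genes Ndufs3 2.29-fold and Ndufs1 2.17-fold lower. Male germ cell fate genes, several of which belong to Nodal signalling, rose in 4 of 6 (5 over the list alone; adjusted p = 6.03e-04), with Nodal 3.07-fold and Ltbp4 2.18-fold higher. That call held with an estimated correlation (adjusted p = 0.0154).

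Genes of the extraembryonic lineages were lower in ESC. Primitive endoderm genes fell in 15 of 26 and rose in 1 (16 and 2 over the list alone; adjusted p = 6.86e-05, but adjusted p = 0.281 with an estimated correlation), with Dab2 8.59-fold (-0.20 and past no test without its _s_at probe set), the collagen gene Col4a1 5.12-fold and Pdgfra 3.08-fold lower. Trophectoderm genes fell in 11 of 21 and rose in 1 (13 and 1 over the list alone; adjusted p = 8.83e-05, but adjusted p = 0.40 with an estimated correlation), with Eomes 12.1-fold, Krt18 8.25-fold and Tspan8 5.77-fold lower. These genes varied among the 3 ICM arrays, with SDs of 2.10 for Eomes and 2.09 for Krt18, and Eomes, Krt18 and Tspan8 lost their calls when only these 2 groups entered the fit. Among pluripotency genes 5 rose and 6 fell of 27 (7 and 6 over the list alone; adjusted p = 0.952). Sox2 was 3.19-fold higher in ESC, Dppa3 3.94-fold and Lats2 2.96-fold lower (Lats2 -1.40 and past no test without ESC replicate 1), and Pou5f1 (-0.05) and Nanog (-0.51) passed no test. Nanog was called without ICM replicate 2 (-0.88) and with all 34 columns (adjusted p = 0.0468).

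In all 2296 genes passed limma's test, 1260 higher and 1036 lower in ESC, 205 and 297 of them by at least 2-fold. Centring each array moved the share of called genes that were higher from 54.9% to 43.1%. The count was 1360 without ESC replicate 1, 1476 without ESC replicate 2, and 776 when only these 2 groups entered the fit. With dim genes left out 827 were higher. The Gapdh 3′ minus 5′ signal was 2.65 ± 0.27 (SD) in ESC and 4.00 ± 0.21 in ICM, with no overlap of arrays, and that of actin 1.56 and 1.55.

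Embryonic germ cell lines were compared with the germ cells that bracket their day of origin, the mean of PGC E11.5 and PGC E13.5 male. Gja1, the gap junction gene connexin 43, was 69.7-fold higher in EGC (6.12 ± 0.22 SE; 3 against 7 arrays). Prps1, an enzyme of nucleotide synthesis, was higher by 4.32 (log2), smooth muscle actin Acta2 19.9-fold, the Nodal co-receptor gene Tdgf1 13.9-fold and annexin gene Anxa1 13.6-fold. Probe sets of Acta2 and Anxa1 were brightest in MEF (16.56 and 16.18). Over all probe sets EGC correlated with MEF at 0.896, PGC E11.5 at 0.877 and PGC E13.5 male at 0.874. Col1a1, at 11.78 in MEF, was 9.48 in EGC, 9.28 in PGC E11.5 and 9.60 in PGC E13.5 male. Whether the rises of fibroblast genes belong to the lines themselves was not tested. Xlr4a was 13.6-fold lower (-3.77 ± 0.31), Dppa3 9.08-fold, Rhox5 7.84-fold, Lats2 7.73-fold and the chromatin remodeller Smarca2 7.32-fold. Lats2 stood at 9.69 ± 0.30 (SD, n = 3) in EGC, 13.73 ± 0.73 in PGC E11.5 (n = 4) and 11.55 ± 0.41 in PGC E13.5 male (n = 3). Its 14.31 on PGC E11.5 replicate 2 was at the highest value of that array, so the size of this difference is uncertain.

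All 8 germ cell genes fell in EGC (8 over the list alone; adjusted p = 1.23e-08), with Kit 6.72-fold and Prdm1 3.18-fold lower. In EGC Ddx4 (3.51) and Dazl (5.92) stood below their levels in MEF (4.63 and 6.06) and Kit (4.72) near its 4.49 there, so the size of these falls may be limited by the lowest readable signal. Glycolysis genes rose in 13 of 19 and fell in 1 (15 and 2 over the list alone; adjusted p = 1.36e-10): Ldha was 12.1-fold, the glucose carrier Slc2a1 6.29-fold, Tpi1 6.17-fold and the hexokinase gene Hk2 4.64-fold higher. Male germ cell fate genes rose in 4 of 6 and fell in 1 (the same over the list alone; adjusted p = 4.46e-04), among them Tdgf1, Lefty1 (3.06-fold) and Nodal (2.40-fold). These 3 calls held with an estimated correlation, with adjusted p-values up to 0.00654.

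Pluripotency genes rose in 14 of 27 and fell in 3 (17 and 3 over the list alone; adjusted p = 7.79e-06, or adjusted p = 0.0528 with an estimated correlation). Klf4 was 8.02-fold, Dppa2 5.28-fold, Fgf4 4.71-fold and Nanog 1.98-fold higher (Nanog 0.35 and past no test against PGC E11.5 alone), whereas Pou5f1 passed no test (0.40). It was called against PGC E13.5 male alone (0.64), with array weights (adjusted p = 0.0188) and with only the compared groups in the fit (adjusted p = 0.00408). Sox2 was 1.39-fold higher, but differed by -0.01 from PGC E11.5 alone, and lost its call without EGC replicate 3 (0.37) and after quantile normalization (0.29). YAP target genes rose in 7 of 15 and fell in 2 (7 and 3 over the list alone; adjusted p = 0.0473, or adjusted p = 0.15 with an estimated correlation): Ccn2 was 6.54-fold, Amotl2 3.79-fold and Ccn1 3.31-fold higher, beside Yap1 itself at 2.26-fold. Immediate early genes rose in 7 of 20 and fell in 1 (8 and 1 over the list alone; adjusted p = 0.00611, or adjusted p = 0.214 with an estimated correlation), with Fos 4.92-fold and Egr1 3.96-fold higher. Mesenchyme genes rose in 11 of 29 and fell in 1 (12 and 1 over the list alone; adjusted p = 0.00712, or adjusted p = 0.154 with an estimated correlation), with Tagln 3.99-fold higher. Imprinted genes rose in 10 of 24 and fell in 3 (11 and 3 over the list alone; adjusted p = 0.0235, or adjusted p = 0.184 with an estimated correlation), with Mest 2.44-fold higher. Maternal and 2-cell stage genes rose in 4 of 9 (4 over the list alone; adjusted p = 0.0265, or adjusted p = 0.0607 with an estimated correlation), with Zp3 2.17-fold higher. In all 2372 genes passed limma's test, 1156 higher and 1216 lower in EGC, 293 and 201 of them by at least 2-fold. Against PGC E11.5 alone 482 were lower by 2-fold, and against PGC E13.5 male alone 471 higher. The 3′ minus 5′ signal of the actin control was 1.86 in EGC, 0.95 in PGC E11.5 and 0.39 in PGC E13.5 male, and that of Gapdh 3.16, 3.48 and 3.57.

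The 2 kinds of cultured line, both male and of the same strain, were compared with each other. Their passage numbers differed, higher in EGC, so origin and passage cannot be told apart here. Ccar1 was 12.4-fold higher in EGC (3.64 ± 0.32 SE; 3 against 2 arrays), Acta2 11.3-fold, the microtubule regulator gene Stmn2 6.97-fold, Alyref, an mRNA export factor, 6.80-fold and Anxa1 6.23-fold. Probe sets of Acta2 and Anxa1 were brightest in MEF (16.56 and 16.18), so high signal of these genes is not particular to EGC. With plain _at probe sets only, Ccar1 differed by 0.46 and passed no test, and Stmn2 by 0.96. Calml4 was 7.69-fold lower in EGC (-2.94 ± 0.28), Kit 7.59-fold (at 4.72 in EGC, near its 4.49 in MEF), Mki67 6.85-fold and Frat2 6.78-fold. Ddx4 was lower too, at 3.51 in EGC, below its 4.63 in MEF, and 6.41 in ESC, near its 6.26 in HSC. All 8 germ cell genes were lower in the germ cell derived line (8 over the list alone; adjusted p = 2.46e-05, or adjusted p = 0.127 with an estimated correlation), with Prdm1 2.31-fold and Dppa3 2.13-fold lower. Pluripotency genes rose in 7 of 27 and fell in 4 (the same over the list alone; adjusted p = 0.996); Pou5f1 (-0.47), Nanog (-0.24) and Sox2 (-0.01) passed no test, and Zfp42 was 2.30-fold lower. Pou5f1 was called with array weights (adjusted p = 0.0364), with only these 2 groups in the fit (adjusted p = 0.0251) and with all 34 columns (adjusted p = 0.0479). In all 3254 genes passed limma's test, 1719 higher and 1535 lower in EGC, 241 and 455 of them by at least 2-fold. The 18S control signal was 14.43 ± 0.18 (SD, n = 3) in EGC and 10.55 ± 0.49 in ESC (n = 2). The Gapdh 3′ minus 5′ signal was 3.16 in EGC and 2.65 in ESC, with no overlap of arrays, while that of actin (1.86 and 1.56) overlapped. Without ESC replicate 2 the count was 2147.

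ICM and PGC E11.5 were compared as embryonic pluripotent groups, although EGC came from germ cells of a later day. They differed in strain and isolation as well as in lineage. Gja1 was 153-fold higher in ICM (7.25 ± 0.24 SE; 3 against 4 arrays), Pramel6 50.2-fold, Calcoco2 43.8-fold, BC053393 34.3-fold and the tetraspanin gene Cd63 21.7-fold. Ccar1 was 30.6-fold lower in ICM (-4.94 ± 0.27), Pdk3 18.2-fold, Rhox6 9.26-fold and the basement membrane gene Nid2 9.19-fold. Peg3 differed by -4.58 on the log2 scale. Ccar1 differed by -0.98 with plain _at probe sets only. Klf4 was higher in ICM by 4.15 on the log2 scale by its brighter probe set, while a dim second one was called lower (-0.50). Nanog was 2.14-fold and Pou5f1 1.60-fold higher in ICM (Pou5f1 passed no test without ICM replicate 3, 0.42, with array weights, 0.56, with a mean of probe sets, 0.22, or with only these 2 groups in the fit, adjusted p = 0.0734), and Lats2 5.20-fold, Kit 3.27-fold and Sox2 3.18-fold lower.

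Primitive endoderm genes were higher in ICM in 15 of 26 and none were lower (15 over the list alone; adjusted p = 1.00e-05, or adjusted p = 0.73 with an estimated correlation), with the laminin gene Lama1 4.71-fold higher and Col4a1 higher by 3.59 (log2). Dab2 was 5.83-fold higher, but differed by -0.24 once probe sets ending in _s_at were left out. Trophectoderm genes rose in 13 of 21 (14 over the list alone; adjusted p = 1.00e-05, or adjusted p = 0.73 with an estimated correlation), with Fabp3 18.2-fold and Eomes 11.7-fold higher, and Krt18 by 3.33 (log2). Eomes and Krt18 varied widely among the ICM arrays, as given for ESC over ICM, so these sizes are uncertain. Oxidative phosphorylation genes rose in 12 of 30 and fell in 1 (the same over the list alone; adjusted p = 0.0204, or adjusted p = 0.73 with an estimated correlation), with Ndufs1 3.11-fold and Uqcrc1 2.50-fold higher. In all 3446 genes passed limma's test, 1547 higher and 1899 lower in ICM, 402 and 316 of them by at least 2-fold. With only these 2 groups in the fit the count was 2253. The 3′ minus 5′ signals were higher in ICM (actin 1.55, Gapdh 4.00) than in PGC E11.5 (0.95 and 3.48).

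A last comparison tested whether the step from embryo to culture differed between the lineages, as the EGC step minus the ESC step. Strain and sex differ between ESC and ICM, and PGC E11.5 was of mixed sex. Strain and sex therefore enter the difference and cannot be told apart from culture. Gja1 differed upward by 115-fold (6.85 ± 0.37 SE), Cd63 65.5-fold, Calcoco2 48.1-fold, Pramel6 41.5-fold and BC053393 24.7-fold. Pramel6 (adjusted p = 0.514) and BC053393 (adjusted p = 0.782) passed no test in EGC over germ cells, so their differences reflect their falls in ESC over ICM. Rhox5 differed downward by 46.9-fold (-5.55 ± 0.22), Pdk3 21.1-fold, Kit 11.9-fold and Peg3 11.2-fold, and Nid2 differed by -3.76. The size for Kit may be limited by its level in EGC (4.72), near that in MEF (4.49). Rhox5 went from 8.08 ± 0.27 (SD, n = 3) in ICM to 10.66 ± 0.04 in ESC (n = 2), and from 11.17 ± 0.05 in PGC E11.5 (n = 4) to 8.02 ± 0.11 in EGC (n = 3).

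Primitive endoderm genes differed upward in 16 of 26 (16 over the list alone; adjusted p = 6.70e-06, or adjusted p = 0.217 with an estimated correlation) and trophectoderm genes in 10 of 21 (10 over the list alone; adjusted p = 3.72e-04, or adjusted p = 0.342 with an estimated correlation), with Krt18 13.6-fold (a size made uncertain by its wide spread among the ICM arrays). In the main camera test neither list passed in EGC over germ cells (adjusted p = 0.0606 and 0.494). Their median differences were 0.115 and 0.058 there, against -0.502 and -0.553 in ESC over ICM, so the upward differences mainly reflect falls in ESC over ICM. Germ cell genes differed downward in 7 of 8 (7 over the list alone; adjusted p = 7.98e-05, or adjusted p = 0.116 with an estimated correlation), and meiosis genes in 4 of 8 (4 over the list alone; adjusted p = 0.0194, or adjusted p = 0.275 with an estimated correlation), with Syce2 4.09-fold. Pluripotency genes differed upward in 13 of 27 and downward in 4 (14 and 7 over the list alone; adjusted p = 0.00286, or adjusted p = 0.275 with an estimated correlation), with Dppa2 15.5-fold and Klf4 11.9-fold. Hippo components differed upward in 7 of 18 and downward in 2 (7 and 3 over the list alone; adjusted p = 0.0143, or adjusted p = 0.116 with an estimated correlation): Amotl2 by 5.25-fold and Yap1 by 2.46-fold upward, and Lats2 by 2.61-fold downward. The Lats2 call was lost without any 1 of PGC E11.5 replicates 1, 2 and 3, PGC E13.5 male replicates 1 and 2, ESC replicates 1 and 2, ICM replicates 1 and 3, and EGC replicates 1 and 3 (-1.55 to -1.14), with each array centred on its median (-1.31) and with only the compared groups in the fit (adjusted p = 0.0573). Immediate early genes differed upward in 8 of 20 and downward in 1 (the same over the list alone; adjusted p = 0.0194, or adjusted p = 0.342 with an estimated correlation), with Fos 14.2-fold. In all 2299 genes passed limma's test, 1077 upward and 1222 downward, 522 and 365 of them by at least 2-fold. Centring each array moved the share upward from 46.8% to 57.9%.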

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

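All tests of explanations below were chosen after the pattern was seen; the counts of other splits and the checks for single arrays far from their group were planned beforehand.

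Of 84 checks of single arrays within groups of 4 to 6, 8 stood apart where chance gives about 4.2 (1 in 20). In PGC E11.5, Eif2s3y was 7.96 on replicate 1 against 7.65 to 7.70 on the others. On replicate 4 of that group Ddx4 was 6.24 (others 6.89 to 6.99), Kit 7.92 (8.68 to 8.78) and the median SD of its differences from its group mates 0.338 (0.199 to 0.221). In SGM, Ddx4 was 4.69 on replicate 3 (others 4.63 to 4.64) and the Gapdh control signal at the 3′ end exceeded that at the 5′ end by 2.75 on replicate 1 (3.15 to 3.22). In MEF, Pou5f1 was 4.99 on replicate 3 (4.32 to 4.49) and Dazl 6.23 on replicate 5 (5.97 to 6.05). On PGC E11.5 replicate 4 the germ cell list lay below the mean of the other 3 arrays by a median of -0.581 and the erythroid list above it by 0.239.

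The step from embryo to line differed between lineages, by the test of the difference itself, for 2299 genes. Strain and sex enter that difference too and cannot be told apart from culture. The 10 named ones were Gja1 (6.85), Cd63 (6.03), Calcoco2 (5.59), Pramel6 (5.38), BC053393 (4.63), Rhox5 (-5.55), Pdk3 (-4.40), Nid2 (-3.76), Kit (-3.57) and Peg3 (-3.49), as log2 differences of EGC minus germ cells from ESC minus ICM.

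A first pattern is in control probe sets that no comparison uses. Their values correlated with those of the other groups at 0.293 on the NSC arrays and 0.347 on the HSC arrays, against 0.97 to 0.995 among the others (correlations across probe sets, which are not independent replicates). If gene values were affected too, windows of genes of the same length should correlate as poorly, but the lowest was 0.612, near the 0.645 of MEF, which argues against it. Less actin RNA is argued against by the ordinary actin beta probe set, at 11.2 or more on these 4 arrays, within the 10.9 to 12.6 of the others. Whether the control values are in another order on these arrays or differ for another reason was not found, and no biological explanation was tested.

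A second pattern is the excess of 2-fold falls from E11.5 to E13.5 germ cells, 479 against 50 rises (624 against 86 without PGC E11.5 replicate 4). A narrower spread of values on the E13.5 arrays is not the whole cause, since quantile normalization left 4.42 falls per rise (from 9.58). A difference in RNA preparation, marked by the 18S signal, may contribute: the 479 genes were lower in EGC than in ESC, which differ likewise in 18S, by a median of -0.719 against 0.06 for other genes, a difference of -0.776. Within groups, however, their mean minus that of the other genes related to 18S only weakly over 18 arrays (Pearson's r = -0.415, Spearman's rho = -0.358, permutation p = 0.112), which did not pass the test. Without the 2 arrays farthest from the median, r was -0.442. The 3′ minus 5′ signal changed by -0.259 for actin and by 0.215 for Gapdh (exact permutation p = 0.262 and 0.314, two-sided), so stronger loss of 5′ sequence cannot be told apart from none with 10 arrays, but falls also outnumbered rises in each sex alone (632 against 55 in male cells and 384 against 101 in female cells), so meiosis in female cells is not the whole cause; the germ cell origin of EGC stays open, untested.

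The last pattern is the higher level of X-linked genes in female germ cells. The spread of chromosome medians is argued against by the autosomes, whose highest median was 0.077 against 0.279 for X. The median of 0.194 that remained without the 20 largest rises decides little about a few strongly changed genes, because a median barely depends on them; the 68.1% of brighter X-linked genes above 0, against 48.0% of autosomal ones, argue against that explanation. Quantile normalization acts alike on the genes of all chromosomes and so could hardly remove the difference. The X-linked minus autosomal median of 0.291 after it therefore decides little about the normalization. A higher dosage of X-linked genes in female germ cells of this stage is a hypothesis that these values leave open; it was found and tested on the same arrays.

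Other splits of the same arrays into groups of the same sizes were counted, by which arrays stand on which side of a comparison; this way of counting was settled after a first run. For pluripotent over somatic 1 of 100 splits, the real one, called as many genes (5273, highest other 196). For the shared higher genes it was also 1 of 100 (34, highest other 0). Germ cells over gonad soma gave 1 of 35 (4141, highest other 2400). E13.5 over E11.5 gave 1 of 100 (4193, highest other 3370) and ICM over germ cells 1 of 35 (3446, highest other 2312). Other splits mix cell types within a group, which widens the spread, and their median count was 0. For shared genes, which must pass every pair of groups, such a count is nearly fixed in advance. These splits therefore show only that arrays of a group resemble each other, and they do not exclude chance. For EGC over germ cells 3 of 100 splits called as many (2372, highest other 3353), a share under 0.05. Which arrays the splits with more genes set apart was not examined. The 10 splits of the E13.5 sexes are too few for a share under 0.05 (1 of 10, 711, highest other 0). Splits planned for ESC over ICM, EGC over ESC and the culture difference were not run, as ESC has only 2 arrays.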

How the results depend on the processing

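The replicate block, quantile normalization, median centring, eBayes with trend and robust, a mean over probe sets and dim genes left out each kept the total of called genes of every comparison within 1.5 times, but by direction 192 lower genes between the sexes became 336 after quantile normalization, 2549 higher genes at E13.5 became 1570 after median centring, and 1260 higher genes in ESC over ICM became 827 with dim genes left out. Array weights gave 1243 between the sexes. Only the compared groups in the fit gave 776 for ESC over ICM and 2253 for ICM over germ cells, and could not be applied to the 2 comparisons of all groups. That setting raised EGC over ESC to 3712 and lowered the count between the sexes to 501. ICM arrays varied most: their median SD of differences from group mates averaged 0.412, against at most 0.368 in another group (HSC). A spread shared by all groups can therefore be too small for comparisons with ICM. The female group alone gave 2602 for E13.5 over E11.5. Shared higher genes numbered 79 without NSC and 52 without HSC; shared lower genes 21 without ICM, 28 without ESC, 36 without SGM, 30 without MEF, 51 without NSC and 67 without HSC, as fewer groups bind the test. Added after seeing the data, all 34 columns gave 20 shared lower genes, and leaving out the NSC and HSC arrays gave 304 higher and 353 lower. Calls on the shift of each gene list went from 65 to 22 with an estimated correlation, and to 64 with the replicate block. With each array left out in turn, 1 result at a time, counts ran from 389 to 740 between the sexes, 1360 to 2359 for ESC over ICM, 2147 to 3014 for EGC over ESC and 8 to 17 for the shared lower genes (a lone ESC array was assumed to vary like the other groups); the other counts stayed within 1.5 times. The X-linked minus the autosomal median, 0.079, ran from 0.063 to 0.087.

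Of 8148 values of named genes under the settings that leave out no single array, 7890 kept direction and side of the threshold, 73 lost the call, 174 gained one and 11 reversed. Those reversed were Yap1, pluripotent over somatic (-0.06 with a mean of probe sets, -0.635 without HSC, -0.892 without the NSC and HSC arrays), Stra8 (-0.135 without PGC E13.5 female), Ccng1 (0.759) and Kit (-0.174) without MEF, and Tet1 (0.00 without the NSC and HSC arrays). Sox2 reversed in EGC over germ cells (-0.008 against PGC E11.5 alone), Igf2 in germ cells over gonad soma (0.066 with plain _at probe sets) and Dab2 in ICM over germ cells (-0.243 with those probe sets, and -0.243 without _s_at probe sets). Apart from the groups and arrays left out, the cause was not tested. With single arrays left out, 7578 of 7697 values kept both, 83 lost the call, 36 gained one and none reversed. Signal near background limits dim genes: the X-linked minus autosomal median was 0.292 with dim genes left out.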

Other observations

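The lists with no call in any comparison were macrophage genes, whose lowest adjusted p was 0.0716 (11 of 15 lower in pluripotent cells), and DNA methylation and demethylation genes. In EGC over germ cells, 4 of 12 members of the latter rose and 2 fell (adjusted p = 0.118); in ESC over ICM, 4 rose and 2 fell (adjusted p = 0.451). Tet1, an enzyme that oxidises methylated DNA, stood at 6.00 in ESC and 6.07 in PGC E11.5, near its 5.91 in MEF and 5.94 in SGM, and may not exceed background there, so its calls against ICM (4.85) are not read as differences in the gene's activity. The EGC over germ cells difference of Dnmt3a, which adds DNA methylation, was 3.14 by its brighter probe set and -0.458 by a dimmer one, both past the test; the gene was singled out after its values were seen, because its probe sets disagree.

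The Hippo kinase gene Lats2 was lower in both lines than in the embryonic pluripotent groups: 13.7 in PGC E11.5, 12.1 in PGC E13.5 female, 11.6 in PGC E13.5 male and 11.4 in ICM, against 9.79 in ESC and 9.69 in EGC. On PGC E11.5 replicates 1, 2 and 3 Lats2 was 14.02, 14.31 and 13.93, at or near the highest values of those arrays (14.15, 14.31 and 14.16). Whether its probe set reads Lats2 alone was not tested, so the size of its differences is uncertain. Kit was lowest in EGC among the pluripotent groups (4.72 ± 0.15, SD, n = 3) and 9.69 ± 0.14 in HSC (n = 2), which were sorted on its protein.

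Among groups labelled as mixed in sex, Eif2s3y in SGM was 3.38 or lower on replicates 1 and 4 and 6.54 or higher on replicates 2 and 3. In NSC it was 4.26 and 4.16. The 18S control signal was 11.04 ± 0.04 in ICM, 10.5 ± 0.49 in ESC, and 12.9 to 15.1 by group mean in EGC, MEF, SGM and the germ cell groups; it was not read on the NSC and HSC arrays, whose control values depart from those of all other arrays. Ccar1, by its brightest probe set, was low in ICM (6.69), ESC (6.78), NSC (6.89) and HSC (5.17), against 9.98 to 11.6 in those 6 groups. No label gives a batch, so whether a batch underlies either difference is open.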
